A study of Drosophila melanogaster with 9 samples.

How the data were processed

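Testes of Drosophila melanogaster males were profiled on 9 Affymetrix expression arrays, 3 each from control flies (red e), flies labelled comr and flies mutant for can. Per the labels' protocols, flies were reared at 25 °C, testes were dissected by hand within a day of eclosion, frozen until enough had been collected and extracted with Trizol, and biotin-labelled cRNA was made from 2 µg of total RNA. The deposited values are the intensity of each probe set on a linear scale, made by the authors with GCOS 1.4 per the submitters' processing notes. The algorithm behind the signal, its background step and any filter are not given in the sources used here. In the values themselves, the mean of each array without the lowest and highest 2% lay at 100, so the arrays had been scaled to a common trimmed mean, and no further normalisation was applied. That scaling sets the level against which every rise and fall is read.

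The array table held 14010 probe sets, of which 44 were control probe sets and left out of the tests. Of the others 12443 carried 1 gene symbol, 327 several and 1196 none, for 10845 genes. Symbols and chromosomes came from the array's annotation and the current gene table, and gene coordinates and the genome build are not given in the sources used here. Probe sequences were not analysed here, so probe sets of near-identical paralogs such as Mst84Da to Mst84Dd may read one another's transcripts. The floor was the highest signal of 23 control probe sets with no spiked target, 20.3. Values were analysed as log2 of signal plus 16 after leaving out the 30% of probe sets with the lowest mean over all 9 arrays, a mean signal of 14.1, which left 9776 probe sets of 8229 genes. With 3 arrays per group the number of arrays limits the precision.

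Each comparison used limma 3.58.1 in R 4.3.3 with 1 coefficient per group over all 9 arrays, a spread moderated with an intensity trend and two-sided tests. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets and a change of at least 2-fold. A rank test of 3 arrays against 3 cannot go below an exact p of 0.1. Comparisons were arrays labelled comr against control, can against control and arrays labelled comr against can, plus the calls common to both mutants, for which 50 simulations without effect kept the 3 controls shared. The replicate numbers are not stated to mark a shared day and did not pair the arrays, so no block was used. Gene lists were tested with camera in limma at a preset correlation of 0.01, with 1 probe set per gene (highest mean) and adjustment over the 25 of 28 lists with at least 3 tested members, and again with an estimated correlation.

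The lists covered tMAC subunits, testis TAFs, their general counterparts, meiotic cell cycle, Mst(3)CGP and tail proteins, sperm chromatin, comet and cup genes, axoneme and sperm motility, sperm leucyl aminopeptidases, testis and general proteasome subunits, testis and general respiratory chain genes, early germline, spermatocyte genes, somatic cyst and hub cells, male accessory gland, ejaculatory duct and bulb, fat body and haemolymph, muscle, haemocytes, neurons, heat shock, immune genes, Polycomb, ribosomal proteins, ribosomal protein paralogs and strain markers. Members without a probe set were left out, so 24 of 69 ribosomal protein genes and 4 of 14 heat shock genes were measured. Genes named were comr, can, aly and the strain markers; up to 3 members per list and comparison with control, those with the largest change among called members whose arrays did not overlap, or where none was called the brightest members as values; the 6 largest falls and rises per comparison with control; and the 8 largest each way between the mutants, among called genes whose brighter group lay above the median signal of 67.5. Any other member named was chosen after its values were seen. Lists, groups, tests, the naming rule and most alternatives were chosen before the data were examined. The rule for lower bounds of fold changes, which needs every array of the dimmer group at or under the floor, was set after the values had been seen.

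Alternatives changed 1 choice each: an offset of 1 or 64, no filter or 50% left out, quantile normalisation, centring on ribosomal protein genes or on array medians, no intensity trend, array weights, only the groups compared, the replicate number as a block, no minimum fold or 4-fold, 1 probe set per gene, an estimated correlation and each array left out. Centring on the 9 spiked hybridisation control probe sets and leaving out the array with most accessory gland signal in each group were chosen after seeing the data. The procedure was tested on simulated data with known changes over 9776 probe sets: it recovered 95.8% to 98.0% of changes of 1.5 on the log2 scale and 98.0% to 100% of larger ones, called 1, 1 and 3 unchanged probe sets in the 3 comparisons, and found the shifted list in each with 0 other lists called. The simulated probe sets varied independently and no array was rescaled. These counts thus do not cover false calls from correlated genes or from scaling. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Raw image files were not analysed here.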

Results

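Expression was measured in hand-dissected adult Drosophila testes on 9 Affymetrix arrays, 3 for each of 3 genotypes. The control flies carried red and e, the marked chromosome on which the can allele was made, and had normal testes per the labels. The arrays labelled comr came from comr[z1340] cn bw males, and the can arrays from males with can[3] on the red e chromosome. Spermatogenesis in both mutants stops at the spermatocyte stage, before the meiotic divisions and before spermatids form. The titles and genotypes of the arrays labelled comr name comr, while their source name and description name aly, a different gene of the same class. Which gene was mutant in these arrays was therefore not settled by the labels, and "labelled comr" stands for that group throughout. The labels do not say that the replicates came from separate dissections, so the p values measure only the spread between these arrays. Their number limits the precision.

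The arrays of each genotype resembled one another more than those of other genotypes. Correlations across probe sets were 0.972 to 0.987 within groups, with medians of 0.420 between control and arrays labelled comr, 0.703 between control and can, and 0.830 between the mutants. The first principal component held 83.1% of the variance and the second 11.3%. Control probe sets that were not spiked reached a signal of at most 20.3, which was taken as the floor, and 59.3% of probe sets in control, 57.2% in arrays labelled comr and 62.8% in can lay above it. The ratio of 3' to 5' signal for GAPDH, a measure of RNA integrity, was 2.59 ± 0.294 (SD, n = 3) in control, 5.99 ± 0.635 in arrays labelled comr and 5.52 ± 1.33 in can. The same ratio for actin was 2.62, 2.43 and 2.57, and for eIF4a 5.22, 6.76 and 3.83. The mean signal of 11 accessory gland genes was 373.8, 192.6 and 55.3 in the control arrays, 157.2, 6.49 and 4.30 in those labelled comr and 228.3, 10.1 and 326.3 in can, although the protocol describes removal of that tissue. Levels are given as array signals, mean ± SD (n = 3 arrays per group), changes are log2 differences of signal plus 16 with their standard error (SE), and p values are two-sided from limma.

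The transcripts of the genes that the labels name were compared first. The comr transcript (CG13493, chromosome 2R), which encodes a subunit of the testis meiotic arrest complex tMAC, gave 17.3 ± 5.63 in control, 33.5 ± 3.04 in the arrays labelled comr and 58.1 ± 9.89 in can. Only 1 control array was above the floor for it. The change was 0.58 (SE 0.15) in the arrays labelled comr, under the 2-fold threshold, and comr rose by 1.16 (SE 0.15, adjusted p = 2.22e-05) in can. The can transcript (CG6577, chromosome 3L), which encodes a testis homolog of the general transcription factor subunit Taf5, rose by 1.92 (SE 0.16, adjusted p = 2.54e-07) from 31.8 ± 8.89 to 163 ± 13.0 in the arrays labelled comr and was 38.0 ± 9.62 in can (log2 change 0.18, SE 0.16). The aly transcript (CG2075, chromosome 3L), for another tMAC subunit, rose from 86.3 ± 5.63 to 546 ± 16.7 in the arrays labelled comr (log2 change 2.46, SE 0.082, adjusted p = 3.61e-11) and was 176 ± 11.4 in can (log2 change 0.91, SE 0.082, short of 2-fold). The comr transcript was thus not below control in the arrays labelled comr, nor the can transcript in can. For comr this cannot decide whether the transcript fell, since control itself lay mostly at or under the floor. For can the control signals of 25.3 to 41.9 lay close above the floor, so only a small fall could have been seen. Both results also depended on the scaling. With the arrays centred on ribosomal protein genes the changes were -0.52, under 2-fold, and -1.14 (adjusted p = 2.85e-05). What the alleles do to their transcripts is not given in the sources used here. Among the strain markers, e gave 40.4, 13.4 and 24.3 (at least 1.97-fold lower in the arrays labelled comr, all at or under the floor, and a log2 change of -0.48 in can) and bw 32.1, 33.4 and 19.0 (log2 change 0.04 and -0.48), with none called. With ribosomal protein centring both were called lower in both mutants, and with array median centring e was called lower in the arrays labelled comr. Without control replicate 1, e passed the threshold in the arrays labelled comr. The median of the strain marker list lay above 0 in the arrays labelled comr only with centring on spiked controls, cn was too dim to test, and red and w had no probe set.

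**Figure D1:**
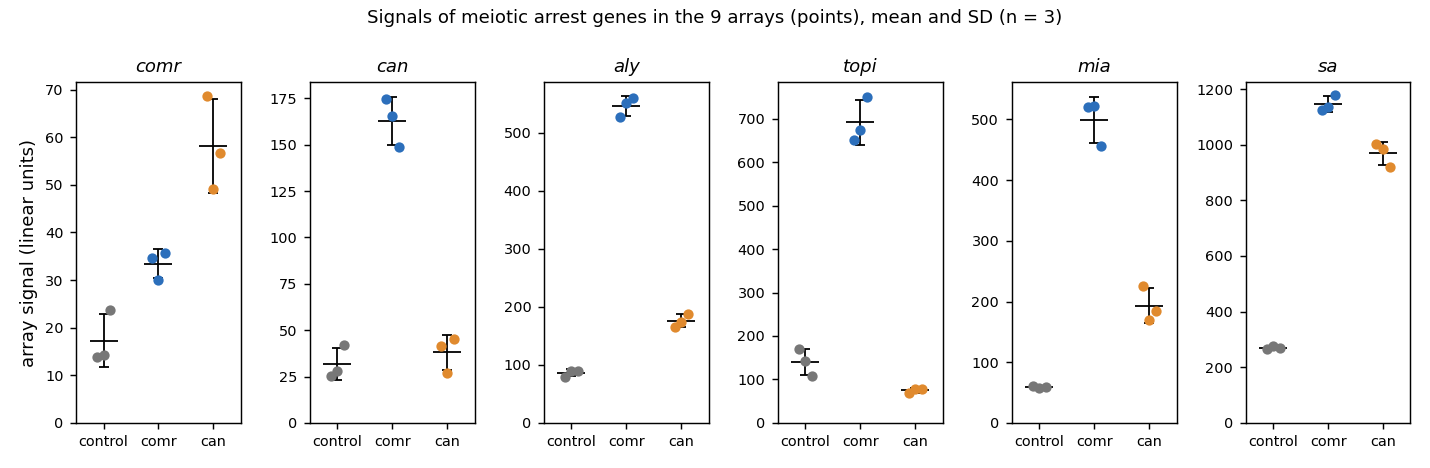
Array signals (linear units, axes from 0) of comr, can, aly, topi, mia and sa in control, arrays labelled comr and can, with 1 point per array and the mean and SD of 3 arrays. In the arrays labelled comr aly reached 526.9 to 558.8 against 79.8 to 89.6 in control, and in can the can transcript stayed at 27.1 to 45.4.

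The comparison of arrays labelled comr with control asked which transcripts differ in level between these testes. Since spermatids do not form in the mutants, whole testes cannot tell missing cells from lower transcript levels within cells. Strain background also differed, cn bw against red e in control, and cannot be told apart from the mutation in this comparison. Several transcripts for building sperm fell to the floor or near it. Mst77F (CG3354, chromosome 3L), a linker-histone-like protein of sperm chromatin, was at least 88.7-fold lower, at 10.8 ± 4.82 against 1799.8 ± 11.7 in control, and dj (CG1980, chromosome 3R), a sperm tail protein, was at least 89.3-fold lower (16 ± 4.01 against 1814 ± 56.7). The post-meiotic cup gene w-cup (CG7363, chromosome 2L) was at least 60.1-fold lower, and robl62A (CG1014, chromosome 3L), a dynein light chain of the roadblock family, fell by 6.33 (SE 0.12, adjusted p = 2.11e-13) to 26.2 ± 5.91 from 3354 ± 68.8. In the other direction, RpL22-like (CG9871, chromosome 2R), a germline paralog of a ribosomal protein, was at least 44.5-fold higher (904 ± 19.9 against 13.6 ± 7.80), and the Polycomb gene esc (CG14941, chromosome 2L) at least 14.5-fold higher. Such bounds divide the geometric mean of the brighter group by the floor where every array of the dimmer group lay at or under it. They hold, here and below, for the values as deposited only, and another scaling of the arrays would move them.

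All 5 lists of sperm and spermatid genes fell in the arrays labelled comr. Of the Mst(3)CGP and tail protein genes, 9 of 11 fell (median -2.12). For tail protein genes camera gave an adjusted p of 5.79e-07 (2.38e-07 to 1.47e-04 in the other settings), and adjusted p = 0.0654 with an estimated correlation. The genes that fell included janB (log2 change -4.22, SE 0.077) and djl, at least 19.2-fold lower, while Mst84Dc (log2 change -0.99, SE 0.088) and ocn (log2 change -0.87, SE 0.068) did not reach 2-fold. All 3 tested sperm chromatin genes fell (median -4.18, or -3.91 with members at their bound): Mst77F, Mst33A, at least 15.1-fold, and Prtl99C (log2 change -2.86, SE 0.10). For sperm chromatin genes camera gave an adjusted p of 0.00480 (8.46e-05 to 0.0338 in the other settings), and adjusted p = 0.0941 with an estimated correlation. Of the comet and cup genes, which are transcribed in spermatids after meiosis, 12 of 14 fell (median -2.75, or -2.67 with 7 members at their bound). For comet and cup genes camera gave an adjusted p of 2.28e-07 (5.80e-08 to 1.47e-04 in the other settings), and adjusted p = 0.0654 with an estimated correlation. Members of this list that fell included c-cup, at least 42.9-fold, and sunz, at least 25.1-fold. Of the axoneme and sperm motility genes 11 of 13 fell (median -3.40, or -3.05 with 7 members at their bound). For axoneme and sperm motility genes camera gave an adjusted p of 5.79e-07 (8.16e-09 to 2.20e-04 in the other settings), and adjusted p = 0.0654 with an estimated correlation. Motility genes that fell included robl22E, at least 30.5-fold lower, and the microtubule protein Tektin-C, at least 21.8-fold. The 3 sperm leucyl aminopeptidases, abundant sperm proteins, all fell (median -4.34). For sperm leucyl aminopeptidases camera gave an adjusted p of 0.00460 (2.94e-04 to 0.0338 in the other settings), and adjusted p = 0.0725 with an estimated correlation. S-Lap7 fell from 5456 ± 92.5 to 180.1 ± 38.4 and S-Lap8 from 3221 ± 94.9 to 825 ± 59.4. In these 5 lists, no member rose. Over the 5 scalings (as deposited, quantile normalisation and 3 centrings) 6 to 11 tail protein, 10 to 14 comet and cup and 11 to 13 axoneme and motility genes were called lower.

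Testis-specific paralogs of housekeeping machines and their general counterparts moved apart. Of the testis proteasome subunits 8 of 12 fell and Rpt3R alone rose (median -2.72, or -2.81 with 6 members at their bound). For testis proteasome subunits camera gave an adjusted p of 0.00339 (2.06e-04 to 0.01 in the other settings), and adjusted p = 0.0654 with an estimated correlation. Prosalpha6T was at least 42.5-fold, Prosbeta4R2 at least 23.5-fold and Prosbeta5R1 at least 22.4-fold lower. Of the general proteasome subunits 9 of 17 rose and none fell (median 1.01, below 0 with the arrays centred on ribosomal protein genes). For general proteasome subunits camera gave an adjusted p of 0.00174 (1.10e-04 to 0.0216 in the other settings), and adjusted p = 0.120 with an estimated correlation. Prosbeta5 was at 845 ± 60.5 against 134 ± 23.9 and Prosbeta2 at 1547 ± 39.9 against 295 ± 23.7. Of the testis respiratory chain paralogs 7 of 11 fell and ATPsynbetaL rose (log2 change 1.30, SE 0.066) (median -2.46). For testis respiratory chain paralogs camera gave an adjusted p of 0.00339 (0.00165 to 0.01 in the other settings), and adjusted p = 0.0654 with an estimated correlation. ATPsynCF6L was at least 43.9-fold lower, and UQCR-14L fell by 3.36 (SE 0.11). Falls were called for 8 to 9 testis proteasome subunits and 7 to 8 testis respiratory chain paralogs over the 5 scalings, with 0 to 3 and 0 to 2 higher. Of the general respiratory chain genes 3 of 15 rose, COX5B, ND-51 and ATPsynCF6 (median 0.92, below 0 with ribosomal protein centring). That share was below the 28.8% of all probe sets called higher in this comparison. The shift of this list thus rests on its median, against 0.34 over all probe sets, and not on its calls. For general respiratory chain genes camera gave an adjusted p of 0.00496 (8.61e-04 to 0.668 in the other settings), and adjusted p = 0.160 with an estimated correlation. Ribosomal protein genes rose in 12 of 24 cases (median 0.98, below 0 when the arrays were centred on these genes themselves). For ribosomal protein genes camera gave an adjusted p of 8.78e-05 (4.02e-07 to 0.116 in the other settings), and adjusted p = 0.317 with an estimated correlation. RpL37A rose from 562 ± 63.1 to 2295 ± 225. Calls higher ranged over the 5 scalings from 3 to 14 for general proteasome subunits, 0 to 12 for general respiratory chain genes and 0 to 23 for ribosomal protein genes, fewest with ribosomal protein and most with spiked-control centring. The ribosomal protein paralogs split, with RpL10Aa and RpS28a at least 37.1-fold and 11.9-fold lower and RpL22-like, RpL37-2 and RpS5b higher among 7 (median 1.00, below 0 with ribosomal protein centring, camera adjusted p = 0.537).

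Genes of the arrest machinery rose. Of the 8 tMAC subunits 7 rose and comr itself did not (median 1.68, or 1.67 with 1 member at its bound). For tMAC subunits camera gave an adjusted p of 0.00564 (2.20e-04 to 0.0170 in the other settings), and adjusted p = 0.0725 with an estimated correlation. The largest rises were those of wuc (log2 change 3.11, SE 0.079, adjusted p = 2.72e-12), aly and the zinc finger protein topi (log2 change 2.20, SE 0.13). All 4 testis TAFs rose (median 2.40). For testis TAFs camera gave an adjusted p of 0.0305 (3.25e-04 to 0.0584 in the other settings), and adjusted p = 0.120 with an estimated correlation. Signals of nht went from 72.4 ± 19.7 to 645 ± 16.3, mia from 59.0 ± 1.95 to 499 ± 37.7 and sa from 270.4 ± 6.0 to 1145 ± 29.3. The general counterparts of both complexes gave 5 rises among 11 (median 1.00, below 0 with ribosomal protein centring, camera adjusted p = 0.0689, with 0.0212 to 0.161 in the other settings). They included Taf6 (log2 change 1.79, SE 0.17), E2f2 (log2 change 1.37, SE 0.11) and mip120, at least 2.23-fold higher. Meiotic cell cycle genes went both ways, 3 down and 3 up of 14 (median -0.15, above 0 with spiked-control centring, camera adjusted p = 0.268). The fallers were fzr2, a testis activator of the anaphase-promoting complex and at least 22.5-fold lower, bol (log2 change -2.59, SE 0.086), an RNA-binding protein of meiotic entry, and twe (log2 change -1.18, SE 0.14), the meiotic Cdc25 phosphatase. The spindle checkpoint kinase Mps1 (log2 change 1.42, SE 0.087), aurB and pelo rose. Over the 5 scalings 3 to 8 tMAC subunits, 2 to 4 testis TAFs, 0 to 9 general counterparts and 0 to 4 meiotic cell cycle genes were called higher, fewest with ribosomal protein centring, and 2 to 8 meiotic cell cycle genes lower.

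Early germline genes rose in 4 of 7 cases (median 1.37, camera adjusted p = 0.192): the gap junction gene zpg (log2 change 2.06, SE 0.17), bam, which ends transit amplification and was at least 5.33-fold higher, the Piwi-family gene aub (log2 change 1.43, SE 0.13) and vas. Among 5 spermatocyte genes Rbp4 (log2 change 2.49, SE 0.091) and kmg rose while Hsp60B, at least 81.4-fold lower, and the testis tubulin betaTub85D (log2 change -3.35, SE 0.094) fell. The median of that list was 0.31, its mean -0.96 and the test pointed down (camera adjusted p = 0.664), and the median turned below 0 with ribosomal protein centring. No somatic cyst or hub cell gene passed among 7 (median -0.09, above 0 with spiked-control centring, camera adjusted p = 0.499). Signals were, for chinmo, 79.9 ± 4.86 against 62.1 ± 2.18 and, for Nrt, 48.2 ± 10.2 against 52.1 ± 9.29. All 4 haemocyte genes rose (median 1.35, camera adjusted p = 0.169). They included the clotting protein gene Hml, at least 4.73-fold, and the type IV collagens vkg (log2 change 1.43, SE 0.17) and Col4a1 (log2 change 1.28, SE 0.17). Of 4 heat shock genes 3 rose, Hsp27, Hsp68 and Hsp26 (median 1.47). For heat shock genes camera gave an adjusted p of 0.0436 (0.0170 to 0.122 in the other settings), and adjusted p = 0.136 with an estimated correlation. Of 6 Polycomb genes 4 rose, esc, Sce (log2 change 1.66, SE 0.10), E(z) and Scm (median 1.35, or 1.33 with bounds, camera adjusted p = 0.0737, with 0.0338 to 0.134 in the other settings). Depending on the scaling 0 to 5 early germline, 0 to 4 haemocyte, 0 to 4 heat shock and 1 to 6 Polycomb genes were called higher, fewest with ribosomal protein centring, which also called 2 early germline genes and 6 of 7 somatic genes lower. The rises were measured in arrays with a GAPDH 3' to 5' ratio of 5.99 against 2.59 in control. The actin ratio was 2.43 against 2.62 and that of eIF4a 6.76 against 5.22.

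Markers of tissues next to the testis gave few calls. Of 7 accessory gland genes the seminal protein gene Acp95EF alone passed (median -1.13, camera adjusted p = 0.279), at 399.7 ± 668 against 1523 ± 999 (log2 change -3.73, SE 1.57, adjusted p = 0.0450), and no member passed when p values were adjusted over the list alone. Its adjusted p was 0.119 without control replicate 1, 0.0934 without control replicate 2, 0.132 without comr replicate 2 and 0.188 without comr replicate 3, in a range of 0.00320 to 0.188 over its alternatives except spiked-control centring, where limma took every spread from the intensity trend alone. Sex peptide, SP, was 66.4 ± 68.3 against 318 ± 327 (log2 change -1.65, SE 0.93) and, among fits without 1 array, passed without control replicate 3 (log2 change -2.66, adjusted p = 0.0131, with 0.0131 to 0.441 over its other alternatives). None of 6 fat body and haemolymph genes passed (median -0.16, above 0 with spiked-control centring, camera adjusted p = 0.368). Signals were, for the storage protein gene Lsp2, 62.7 ± 18.5 against 87.7 ± 58.6 and, for Obp99b, 37.0 ± 6.13 against 46.0 ± 15.9. Of 8 muscle genes the paramyosin gene Prm rose, at least 5.16-fold, and the titin-like sls fell, at least 1.5-fold and short of the threshold without control replicate 2 (log2 change -0.99) (median 0.54, below 0 with ribosomal protein centring, camera adjusted p = 0.537). The antimicrobial peptide gene Mtk, at least 1.74-fold higher, was the only immune gene of 4 to pass (median 0.11, or -0.04 with it at its bound, and below 0 with ribosomal protein or array median centring, camera adjusted p = 0.937). Single genes stood for ejaculatory duct (Gld, log2 change 0.36, SE 0.28, below 0 with ribosomal protein centring) and neurons (nSyb, log2 change 0.18, SE 0.25, below 0 with ribosomal protein or array median centring), too few for a list test. Ribosomal protein centring called 6 of 7 accessory gland, all 6 fat body, 2 of 8 muscle and 2 of 4 immune genes lower and none of these lists' genes higher. Spiked-control centring called 5 muscle genes higher and 2 accessory gland genes lower, and quantile normalisation called no accessory gland gene.

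Over all probe sets tested, 1613 of 9776 (16.5%) fell and 2813 (28.8%) rose in the arrays labelled comr, from 1449 and 2479 genes. Genes at the floor have no order among themselves. The 6 bright genes with the lowest fitted changes were CG12860, at least 208-fold, the phosphoglycerate mutase paralog Pglym87, at least 122-fold, and CG3213, at least 123-fold. The others were CG4691, at least 151-fold, CG8701, which fell by 7.02 (SE 0.082) with 2 arrays labelled comr above the floor, and CG4983, at least 107-fold. With RpL22-like, those with the highest were betaNACtes1, a testis paralog of the nascent polypeptide-associated complex (log2 change 4.17, SE 0.15), CG9360, at least 24.6-fold, the nucleoporin Nup107, at least 16.4-fold, mdlc (log2 change 3.67, SE 0.20, with 2 control arrays above the floor) and esc. Of the 25 lists tested 13 passed the threshold, 9 of them in every other setting with the preset correlation, and 0 passed with an estimated correlation. Counts per list were equal when p values were adjusted over the list alone, except for the accessory gland. The balance of rises and falls depended on the scaling: centring on ribosomal protein genes moved the median of all genes by -1.10, centring on array medians by -0.18 and on spiked controls by 0.51, with 9.43%, 54.6% and 77.5% of calls then being rises against 63.6%.

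**Figure D2:**
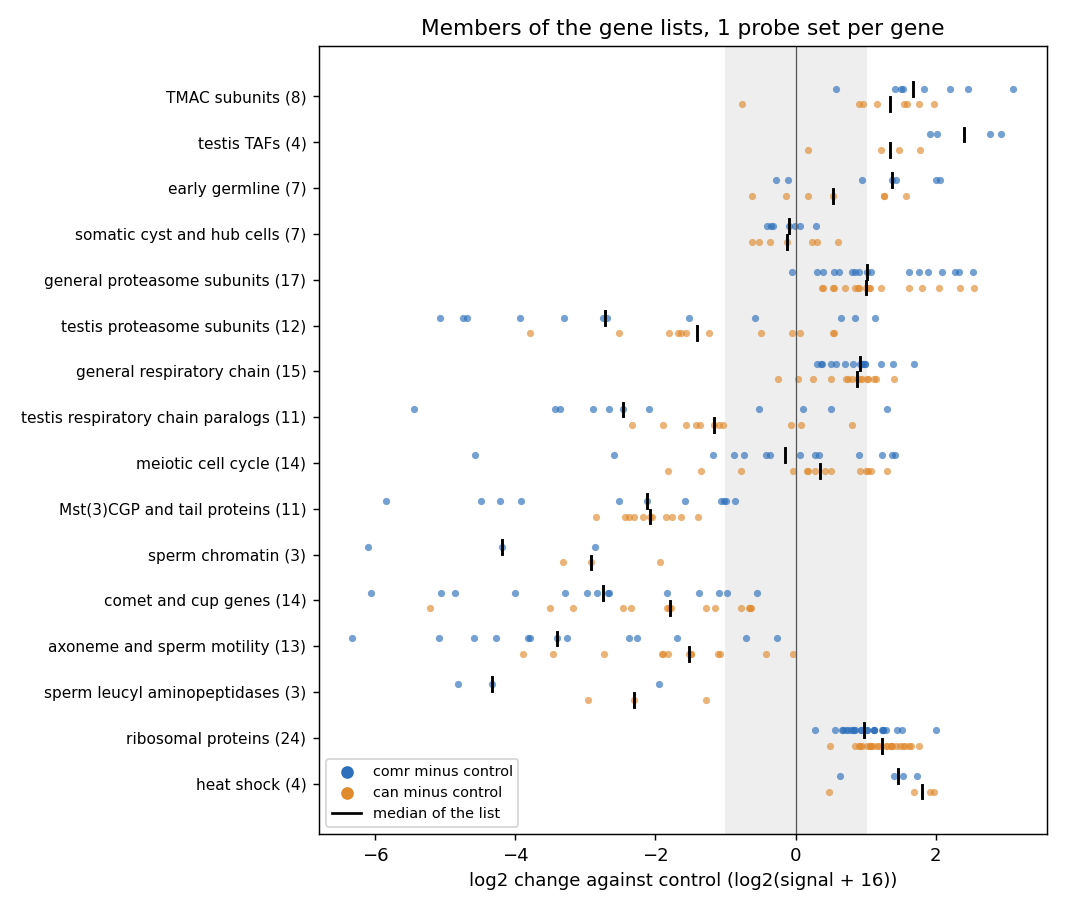
Log2 change against control (signal plus 16) of each tested member of 16 gene lists, in arrays labelled comr and in can, with the median of each list as a black line and changes under 2-fold shaded. Medians of the 5 lists of sperm and spermatid genes lay between -4.34 and -1.52, those of tMAC subunits and testis TAFs between 1.35 and 2.40, and centring on ribosomal protein genes turned the medians of general proteasome, general respiratory chain and ribosomal protein genes below 0 in both mutants and those of early germline and meiotic cell cycle genes below 0 in can, while spiked-control centring turned meiotic cell cycle genes in arrays labelled comr and somatic genes in both mutants above 0.

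The comparison of can with control asked which transcripts differ in level in testes that lack the testis TAF encoded by can. Here too a fall can come from missing cells or from lower levels within cells. Sperm transcripts fell here as well, to low but mostly measurable levels. Mst77F fell by 3.32 (SE 0.13, adjusted p = 4.02e-10) to 167 ± 22.2 from 1799.8 ± 11.7, robl62A fell by 3.90 (SE 0.12) to 212 ± 31, and the sperm peptidase S-Lap7 fell by 2.96 (SE 0.13) to 689 ± 70.7 from 5456 ± 92.5. RpL22-like was at least 45.2-fold higher (919 ± 64 against 13.6 ± 7.80), and the spermatocyte RNA-binding protein gene Rbp4 rose by 2.16 (SE 0.091).

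All 11 Mst(3)CGP and tail protein genes fell in can (median -2.08). For tail protein genes camera gave an adjusted p of 1.09e-08 (5.01e-10 to 3.91e-05 in the other settings), and adjusted p = 0.0465 with an estimated correlation. Tail protein genes that fell included janB (log2 change -2.85, SE 0.077), djl (log2 change -2.44, SE 0.12) and ocn (log2 change -2.37, SE 0.068). The 3 sperm chromatin genes all fell (median -2.91). For sperm chromatin genes camera gave an adjusted p of 0.00272 (1.08e-04 to 0.0396 in the other settings), and adjusted p = 0.0777 with an estimated correlation. Mst33A was at 26.7 ± 2.35 against 308 ± 47.9 and Prtl99C at 184 ± 15.5 against 749.5 ± 5.86. Of the comet and cup genes 10 of 14 fell (median -1.79). For comet and cup genes camera gave an adjusted p of 3.12e-08 (1.39e-09 to 2.32e-04 in the other settings), and adjusted p = 0.0465 with an estimated correlation. The largest falls were those of w-cup (log2 change -5.22, SE 0.14, with 1 can array above the floor), sunz (log2 change -3.51, SE 0.12) and schuy (log2 change -3.18, SE 0.090). In contrast, c-cup was 499.6 against 871 (log2 change -0.78, SE 0.10) and did not reach 2-fold. Axoneme and sperm motility genes fell in 11 of 13 cases (median -1.52), such as robl37BC (log2 change -3.46, SE 0.091) and the dynein heavy chain Dhc36C (log2 change -2.73, SE 0.11). For axoneme and sperm motility genes camera gave an adjusted p of 6.07e-07 (1.69e-07 to 0.00132 in the other settings), and adjusted p = 0.0571 with an estimated correlation. The 3 sperm leucyl aminopeptidases all fell (median -2.30). For sperm leucyl aminopeptidases camera gave an adjusted p of 0.00272 (5.92e-04 to 0.0394 in the other settings), and adjusted p = 0.0652 with an estimated correlation. S-Lap8 fell to 640.4 ± 39.5 from 3221 ± 94.9 and S-Lap5 to 357 ± 9.80 from 888 ± 71.2. No member of these 5 lists rose. By scaling 8 to 14 comet and cup genes, 9 to 13 axoneme and motility genes and 2 to 3 aminopeptidases were called lower.

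Testis paralogs and general genes again moved apart in can. Of the testis proteasome subunits 7 of 12 fell and none rose (median -1.40). For testis proteasome subunits camera gave an adjusted p of 0.00272 (0.00139 to 0.00511 in the other settings), and adjusted p = 0.0606 with an estimated correlation. The largest falls were those of Prosbeta4R2 (log2 change -3.79, SE 0.15, with 2 can arrays above the floor), Prosalpha6T (log2 change -2.52, SE 0.11) and Prosbeta4R1. General proteasome subunits rose in 9 of 17 cases (median 1.01, below 0 with ribosomal protein centring). For general proteasome subunits camera gave an adjusted p of 9.33e-05 (2.41e-06 to 0.00388 in the other settings), and adjusted p = 0.0777 with an estimated correlation. Prosalpha6 rose to 1187 ± 117 from 189 ± 16.3. Of the testis respiratory chain paralogs 8 of 11 fell (median -1.17). For testis respiratory chain paralogs camera gave an adjusted p of 7.11e-04 (4.71e-04 to 0.00584 in the other settings), and adjusted p = 0.0571 with an estimated correlation. Of these 5 to 10 were called lower over the 5 scalings, with 1 called higher under spiked-control centring, and 6 to 10 testis proteasome subunits were called lower. COX4L was at 336 ± 18.3 against 1765 ± 107, and others were COX7AL (log2 change -1.89, SE 0.13) and ND-51L2 (log2 change -1.57, SE 0.11). General respiratory chain genes rose in 5 of 15 cases (median 0.87, below 0 with ribosomal protein centring). For general respiratory chain genes camera gave an adjusted p of 0.0114 (6.28e-04 to 0.968 in the other settings), and adjusted p = 0.208 with an estimated correlation. The genes that rose were ND-20 (log2 change 1.4, SE 0.11), COX5B, ND-51, ATPsynCF6 and blw, and ND-51 changed by 0.95, under 2-fold, without control replicate 1. Of 24 ribosomal protein genes 19 rose (median 1.24, below 0 when centred on these genes themselves). For ribosomal protein genes camera gave an adjusted p of 5.24e-07 (6.35e-10 to 7.67e-05 in the other settings), and adjusted p = 0.225 with an estimated correlation. RpS12 rose from 667 ± 56.6 to 2119 ± 141. The scalings gave 2 to 13 general proteasome subunits, 0 to 11 general respiratory chain genes and 0 to 23 ribosomal protein genes called higher, fewest with ribosomal protein centring, which also called 3 general respiratory chain genes lower, and most with spiked-control centring. Array medians gave 1 general respiratory chain gene. Of the ribosomal protein paralogs 5 of 7 rose, and RpL10Aa (log2 change -3.33, SE 0.096) and RpS28a (log2 change -2.69, SE 0.21, with 1 can array above the floor) fell (median 1.07, below 0 with ribosomal protein centring, camera adjusted p = 0.394, with 0.0155 to 0.525 in the other settings).

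Arrest genes rose in part in can. Of 8 tMAC subunits 5 rose (median 1.35, or 1.23 with 1 member at its bound). For tMAC subunits camera gave an adjusted p of 0.0349 (0.00373 to 0.145 in the other settings), and adjusted p = 0.120 with an estimated correlation. The subunits that rose were wuc (log2 change 1.97, SE 0.079), Caf1-55 (log2 change 1.75, SE 0.079), mip40, comr and achi, at least 2.45-fold. In contrast, topi was 75.0 ± 5.18 against 140.0 ± 30.6 (log2 change -0.76, SE 0.13). This fall was short of 2-fold, but passed it with array median centring, which moved changes in can by -0.26. Of 4 testis TAFs sa (log2 change 1.78, SE 0.063), mia (log2 change 1.47, SE 0.10) and nht (log2 change 1.23, SE 0.13) rose (median 1.35, camera adjusted p = 0.122, with 0.02 to 0.182 in the other settings). Of 11 general counterparts Taf6 (log2 change 1.96, SE 0.17), Taf5, E2f2 and mip120, at least 1.55-fold, rose (median 0.78, or 0.70 with bounds, below 0 with ribosomal protein centring, camera adjusted p = 0.122). Among 14 meiotic cell cycle genes fzr2 (log2 change -1.82, SE 0.11) and bol (log2 change -1.35, SE 0.086) fell and Cks85A (log2 change 1.31, SE 0.11), CycB (log2 change 1.07, SE 0.097) and aurB rose (median 0.35, below 0 with ribosomal protein centring, camera adjusted p = 0.790). Early germline genes gave 3 rises of 7, bam, at least 3.74-fold, zpg (log2 change 1.26, SE 0.17) and aub (log2 change 1.26, SE 0.13) (median 0.53, below 0 with ribosomal protein centring, camera adjusted p = 0.571). Of 5 spermatocyte genes betaTub85D (log2 change -2.69, SE 0.094) and Hsp60B (log2 change -2.51, SE 0.080) fell and Rbp4 rose (median -0.09, above 0 with quantile normalisation or spiked-control centring, camera adjusted p = 0.521). Hsp26 (3519.8 ± 219 against 886 ± 50.4), Hsp68 and Hsp27 rose among 4 heat shock genes (median 1.81), in arrays with a GAPDH 3' to 5' ratio of 5.52 against 2.59 in control. The actin ratio was 2.57 against 2.62 and that of eIF4a 3.83 against 5.22. For heat shock genes camera gave an adjusted p of 0.0206 (3.54e-04 to 0.0446 in the other settings), and adjusted p = 0.106 with an estimated correlation. Of 6 Polycomb genes Sce (log2 change 2.12, SE 0.10) and esc, at least 3.79-fold, rose (median 0.72, or 0.62 with bounds, below 0 with ribosomal protein centring, camera adjusted p = 0.122, with 0.0485 to 0.187 in the other settings). These rises all depended on the scaling. With ribosomal protein centring no member of these 8 lists was called higher, the medians of tMAC subunits and testis TAFs were 0.03 and 0.03, and 1 tMAC subunit, 1 testis TAF, 3 general counterparts, 3 early germline, 3 spermatocyte and 7 meiotic cell cycle genes were called lower. With spiked-control centring 7 tMAC subunits, 3 testis TAFs, 7 general counterparts, 5 meiotic cell cycle, 3 early germline and 4 Polycomb genes were called higher.

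Cell types other than the germline gave few calls in can. None of 7 somatic cyst and hub genes passed (median -0.13, or -0.11 with bounds, above 0 with spiked-control centring, camera adjusted p = 0.631), with chinmo at 81.5 ± 12.5 and Nrt at 46.3 ± 7.13. None of 7 accessory gland genes passed (median -0.02, above 0 with spiked-control centring, camera adjusted p = 0.631). Acp95EF was 1438 ± 1274 against 1523 ± 999 and SP 184 ± 149 against 318 ± 327. The fat body list had none of 6 (median 0.24 and mean 0.20, while its test pointed down, camera adjusted p = 0.926), and its median was below 0 with ribosomal protein or array median centring. Lsp2 was 110.0 against 87.7 and Obp99b 56.9 against 46.0. Of 4 haemocyte genes the peroxidasin gene Pxn (log2 change 1.38, SE 0.24, with 1 control array above the floor) and vkg (log2 change 1.02, SE 0.17) rose (median 0.96, below 0 with ribosomal protein centring, camera adjusted p = 0.383). The change of vkg was 1.00 without control replicate 2, 0.85 without control replicate 3 and 0.96 without can replicate 3, each under 2-fold before rounding. Of 8 muscle genes Prm rose, at least 3.81-fold (median 0.18, below 0 with quantile normalisation, ribosomal protein or array median centring, camera adjusted p = 0.734). Of 4 immune genes Mtk rose, at least 2.15-fold (median 0.33, or 0.31 with bounds, below 0 with ribosomal protein centring, camera adjusted p = 0.790). Gld gave 0.12 (SE 0.28), below 0 with ribosomal protein or array median centring, and nSyb was 7.97 against 28.1, at least 1.28-fold lower with every can array at or under the floor. It was not called, but passed without can replicate 3 and with array median or ribosomal protein centring. Ribosomal protein centring also called Gld, 6 of 7 somatic, 4 of 6 fat body, 5 of 8 muscle, 2 of 4 immune and 1 of 4 haemocyte genes lower and none of these higher, and spiked-control centring called 3 haemocyte, 2 immune and 1 accessory gland genes higher.

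In all, 1258 of 9776 probe sets (12.9%) fell and 2024 (20.7%) rose in can, from 1137 and 1764 genes. The 6 bright genes with the lowest fitted changes were scpr-B, at least 62.6-fold, the proton pump subunit paralog Vha36-2, at least 37.4-fold, w-cup, CG15638, at least 35.9-fold, CG10317 (log2 change -4.95, SE 0.17) and the acylphosphatase gene Acyp (log2 change -4.87, SE 0.16), the last pair with 1 can array above the floor each. With RpL22-like, those with the highest were the amylase gene Amy-d, at least 20.4-fold, CG7214, at least 18.4-fold, betaNACtes1 (log2 change 3.6, SE 0.15), CG14667, at least 16.4-fold, and the G protein gene Galphaf, at least 10-fold. Signals of Amy-d (448 ± 226) and CG7214 (393 ± 146) varied widely between the can arrays, and the cause of this spread was not tested. Of 25 lists 12 passed, 10 of them in every other setting with the preset correlation, and 2 with an estimated correlation, the Mst(3)CGP and comet and cup lists. Counts per list were equal when p values were adjusted over the list alone. With ribosomal protein centring nht, Taf5, mip120, Cks85A, COX5B, ND-51, zpg, aub, vkg and comr, called higher here, lay below 0. That centring moved the median of all genes by -1.32, centring on array medians by -0.26, quantile normalisation by -0.16 and spiked controls by 0.35, with rises making up 1.74%, 44.9%, 54.1% and 77.2% of calls against 61.7%.

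Changes in both mutants were then set side by side, to ask how far the arrest programmes overlap. Sperm genes such as Mst77F, janB and robl62A fell in both, and RpL22-like, betaNACtes1, Rbp4 and sa rose in both. Of the probe sets tested 1162 fell in both mutants and 1697 rose in both, while 8 were called in opposite directions. Independent lists of these sizes would share 207.6 and 582.4, and simulations with no effect and shared controls shared 0 and 0. Without true changes, calls in either comparison are rare by construction, so these simulated counts cannot show how far shared controls raise the overlap. Across probe sets, which are not independent replicates, the changes correlated at 0.885 against 0.513 in 50 simulations with no effect, where the shared controls alone give a correlation, and their covariance was 1.68 against 0.0167, a difference of 1.66. Signs matched for 88.1% of probe sets against 66.7%. The 3 control arrays could not be divided into parts of at least 2 arrays, so part of the excess over independent lists may come from the shared controls, a part that the difference of covariances leaves out.

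**Figure D3:**
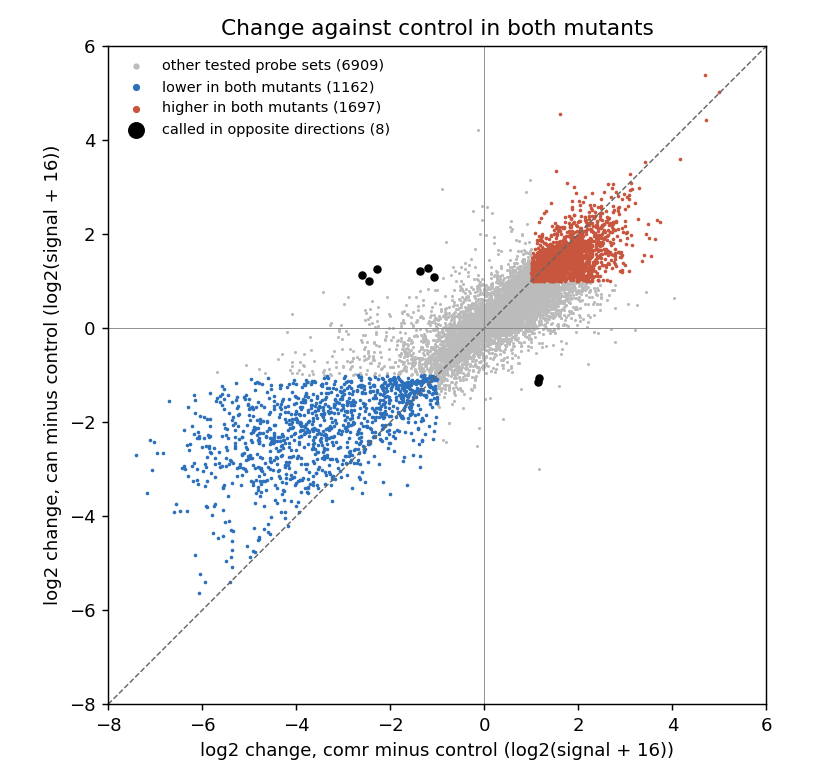
Log2 change against control (signal plus 16) of each of 9776 probe sets in arrays labelled comr (horizontal) and can (vertical), with the dashed line marking equal change. 1162 probe sets were lower in both mutants, 1697 higher in both and 8 called in opposite directions, and most falls lay above the line, with medians of -3.40 in arrays labelled comr against -1.99 in can among those lower in both.

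The direct comparison of arrays labelled comr with can asked whether arrest genes of both kinds act alike. Strain background differed between these groups too, so its effects cannot be told apart from those of the mutations. Some sperm transcripts were lower still in the arrays labelled comr, such as Mst77F at 10.8 ± 4.82 against 167 ± 22.2 in can and dj at 16 ± 4.01 against 354 ± 1.15, and others were higher, such as ocn (log2 change 1.5, SE 0.068). Arrest genes higher there included topi, at 692 ± 51.8 against 75.0 ± 5.18 (log2 change 2.96, SE 0.13, adjusted p = 1.77e-09), aly, higher by 1.55 (SE 0.082), and can, by 1.74 (SE 0.16). Since choosing probe sets by their call in 1 mutant favours a larger change there, both choices are given, the one by can added after the data had been seen. Among those that fell in the arrays labelled comr, the median change was -2.79 there and -1.57 in can, with a smaller change in can for 91.8%, and 881 were called lower than in can against 13 higher. Among those that fell in can, the medians were -3.25 and -1.90, with a smaller change in can for 81.8%, and 626 were called lower in the arrays labelled comr than in can against 30 higher. Falls were thus larger in the arrays labelled comr by either choice. Rises differed less: medians were 1.49 and 1.13 among those that rose in the arrays labelled comr (smaller in can for 82.3%, 363 called higher than in can and 9 lower), and 1.55 and 1.37 among those that rose in can (smaller in can for 59.2%, 99 called higher and 66 lower).

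The 8 bright genes with the lowest fitted changes against can, again with no order among those at the floor, were the spermatogenesis gene bb8, at least 32.0-fold, the sugar transporter gene sut4, at least 28.6-fold, CG13747 (log2 change -4.74, SE 0.084) and CG3213, at least 23.1-fold. The others were CG12860, at least 31.6-fold, CG12126, at least 22.9-fold, the phosphatase inhibitor gene Ppi1, at least 32.1-fold, and CG8701 (log2 change -4.59, SE 0.082). For CG13747 and CG8701, 2 arrays labelled comr were above the floor each. The 8 with the highest were CG9360 (log2 change 3.41, SE 0.14), the glutathione transferase GstD5 (log2 change 3.23, SE 0.12), Tmx3 (log2 change 3.09, SE 0.13, with 2 can arrays above the floor), topi, the serpin gene Spn77Bb, at least 3.66-fold (adjusted p = 0.0319), CG3347 (log2 change 2.76, SE 0.10), the small nucleolar RNA host gene Uhg1, at least 8.95-fold, and CG7907 (log2 change 2.56, SE 0.088). For Spn77Bb the adjusted p was 0.111 without comr replicate 1, 0.137 without comr replicate 2, and 0.0709, 0.0737 and 0.0742 without can replicates 1, 2 and 3, in a range of 9.21e-04 to 0.137 over its alternatives except spiked-control centring.

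Of the lists, testis TAFs were higher in arrays labelled comr than in can for 3 of 4 members, nht, can and mia (median 1.5). For testis TAFs camera gave an adjusted p of 0.0243 (0.00815 to 0.0355 in the other settings), and adjusted p = 0.204 with an estimated correlation. Sperm chromatin genes were lower for 2 of 3, Mst77F and Mst33A (median -1.27, or -0.92 with bounds). For sperm chromatin genes camera gave an adjusted p of 0.0244 (0.0119 to 0.0462 in the other settings), and adjusted p = 0.204 with an estimated correlation. Axoneme and motility genes were lower for 8 of 13 and higher for Dhc36C (log2 change 1.04, SE 0.11) (median -1.36, or -1.0 with bounds), and testis proteasome subunits lower for 7 of 12 (median -1.32, or -1.50 with bounds). For axoneme and sperm motility genes camera gave an adjusted p of 4.26e-04 (9.97e-06 to 0.00223 in the other settings), and adjusted p = 0.204 with an estimated correlation. For testis proteasome subunits camera gave an adjusted p of 0.0310 (0.00700 to 0.0606 in the other settings), and adjusted p = 0.204 with an estimated correlation. No ribosomal protein gene of 24 was called, though the list as a whole passed (median -0.24), with an adjusted p of 0.0576 without comr replicate 1 and 0.0566 without can replicate 1. For ribosomal protein genes camera gave an adjusted p of 0.0243 (0.00502 to 0.703 in the other settings), and adjusted p = 0.603 with an estimated correlation. The ribosomal protein paralogs (median -0.50, or -0.45 with bounds, camera adjusted p = 0.0521) passed without control replicate 3 (adjusted p = 0.0467) or comr replicate 3 (adjusted p = 0.0446), with a range of 0.0329 to 0.225 in the other settings. Short of the threshold were tMAC subunits, with topi, aly and wuc higher (median 0.26, camera adjusted p = 0.0712, with 0.0226 to 0.106 in the other settings), and meiotic cell cycle genes, with fzr2, CycB, twe and bol lower (median -0.39, camera adjusted p = 0.0712, with 0.0327 to 0.178 in the other settings). So were comet and cup genes, with 7 of 14 lower and f-cup and soti higher (median -0.99, or -0.57 with bounds, camera adjusted p = 0.0712, with 0.0119 to 0.193 in the other settings), and tail protein genes, with 4 of 11 lower and Mst98Cb and ocn higher (median -0.35, camera adjusted p = 0.5). Camera adjusted p was 0.201 for the sperm aminopeptidases (median -1.86, adjusted p of 0.0146 to 0.255 in the other settings), 0.155 for the testis respiratory paralogs (median -1.29, adjusted p of 0.0190 to 0.204), and 0.364 for the general respiratory chain (median 0.08). It was 0.261 for the general counterparts (median 0.29), 0.0724 for early germline genes (median 0.43, adjusted p of 0.0360 to 0.178 in the other settings) and 0.261 for haemocyte genes (median 0.40). Polycomb genes gave 0.284 (median 0.35), muscle genes 0.453 (median 0.31), fat body genes 0.295 (median -0.49, or -0.45 with bounds) and accessory gland genes 0.466 (median -1.33, adjusted p of 0.00759 to 0.733 in the other settings). The adjusted p was 0.5 for heat shock genes (median -0.18) and 0.726 for immune genes (median -0.17), both medians above 0 with ribosomal protein centring. Median, mean and test differed in sign for the general proteasome (median -0.01, above 0 in each of the other 4 scalings, mean 0.06, test up, camera adjusted p = 0.869), spermatocyte genes (median 0.33, mean -0.52, test down, camera adjusted p = 0.911) and somatic genes (median 0.01, mean -0.05, test down, camera adjusted p = 0.874).

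Between the mutants 1001 probe sets (10.2%) were lower and 436 (4.46%) higher in arrays labelled comr, from 925 and 389 genes. Counts per list were equal when p values were adjusted over the list alone, 5 of 25 lists passed, 3 of them in every other setting with the preset correlation, and 0 passed with an estimated correlation. Centring on ribosomal protein genes moved the median of all genes by 0.22 and on spiked controls by 0.16, and raised the share of higher calls from 30.3% to 48.5% and 43.4%.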

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

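The tests of array scaling, of a uniform gain of remaining cell types, of normal testis RNA mixed into can and of the comr or aly label were chosen after the results they bear on had been seen, and the scoring of the uniform gain test was revised once its value was known without changing its verdict.

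More probe sets rose than fell in both mutants. Centring the arrays on ribosomal protein genes left 1.74% of calls as rises in can and 9.43% in arrays labelled comr, while centring on spiked controls gave 77.2% and 77.5%, so the scaling may set this balance and the tables hold no reference that decides it. If the loss of later germ cells had raised all remaining cell types alike, early germline and somatic genes should have moved together. Among members above 2 times the floor in at least 1 group, which a change can itself decide, 7 early germline genes changed by a mean of 1.06 in arrays labelled comr against -0.03 for 5 somatic genes (two-sided exact permutation p = 0.0442, 792 arrangements), but by 0.58 against 0.08 in can (exact permutation p = 0.253). Over all 7 and 7 tested members the means were 1.06 against -0.12 (exact permutation p = 0.0134, 3432 arrangements) and 0.58 against -0.07 (exact permutation p = 0.0962). A p of 0.253 or 0.0962 does not show that the groups moved alike, and the few genes keep this explanation open. Array scaling, a changed mix of cells and higher transcript levels within spermatocytes cannot be told apart here.

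Falls in can lay between control and arrays labelled comr, with medians of -1.57 and -2.79 among probe sets that fell in the latter and of -1.90 and -3.25 among those that fell in can. A single share of normal testis RNA in the can arrays, with no such transcripts made in can testes, would leave 1 common ratio to control. Over 502 probe sets bright in control and at the floor in arrays labelled comr, the 90th percentile of that ratio was at least 8.32 times the 10th in every can array. For the group mean the 10th and 90th percentiles were 5.00% and 40.5% of control, with 56 probe sets at the floor and 27 above 50% of control. This argues against such mixing as the only source. A small share beside transcripts made in can testes stays possible, since the probe sets were chosen by control and arrays labelled comr alone. A compression of small values could tie the ratio to the control signal, but Spearman's rho across these probe sets was -0.0862, which shows no such tie. A compression that follows the can signal was not tested, so this rho does not decide the question. A difference between the genotypes stays open and was not tested, since strain background differs with them.

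The labels of the arrays labelled comr disagree on the mutated gene. The comr transcript was lower in them than in can by a log2 difference of -0.58 (adjusted p = 0.00800), the lowest difference of 12 arrest gene transcripts, while aly was higher by 1.55. With comr at 33.5 in these arrays, less than 2 times the floor, and the effect of either allele on its transcript not given in the sources used here, the tables do not settle whether these arrays could hold aly mutant RNA, and both labels stay open.

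Other splits of the arrays were counted for each comparison, each fitted to its 6 arrays alone. Each count of splits that reached a real value includes the real grouping itself. Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05: 1 of 10 gave as many calls as the real 4426 for arrays labelled comr against control (highest other 0), 1 of 10 as many as 3282 for can (highest other 0) and 1 of 10 as many as 1440 between the mutants (highest other 5), where the fit to all 9 arrays gave 1001 and 436. For lists, 2 of 10 splits reached 13 in arrays labelled comr (highest other 13), 2 of 10 reached 12 in can (highest other 12) and 1 of 10 reached 5 between the mutants (highest other 3). A set of 100 splits of the 9 arrays held the real grouping and otherwise random ones. In 4 of these, as many probe sets were called the same way in both comparisons as the real 2859. The highest other value was 3201. All 4 kept the control arrays together, and splits that broke up every genotype in the shared group gave 0. This count thus follows from how often a draw keeps a genotype whole, and says nothing on chance. A correlation as large as 0.885 came from 46 of 100 splits, with 0.982 as the highest other, so chance cannot be excluded for that value by the splits. They mix arrays of different genotypes, and simulations with no effect reached 0.574 at most.

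The GAPDH ratio of 3' to 5' signal was 5.99 in arrays labelled comr and 5.52 in can, above the 2.59 of control, in control probe sets that the comparisons did not use. The actin ratio was 2.43 and 2.57 against 2.62 in control, and that of eIF4a 6.76 and 3.83 against 5.22. The signal of Gapdh1 itself rose from 182 to 610 and 575. The GAPDH ratio alone thus does not show poorer RNA in the mutants. In arrays labelled comr the eIF4a ratio also lay above control without overlap (5.77 to 7.41 against 4.99 to 5.55). The actin ratio did not, so poorer RNA in arrays labelled comr stays open. A total of 8 probe sets were called in opposite directions against control, with a called difference between the mutants. Where every array of a group lay at or under the floor the fold is only bounded, and the fitted difference beside the bound is not a measured size. CG18788 fell from 45.9 to 11.2 in arrays labelled comr and rose to 134 in can, at least 6.55-fold apart (fitted difference -2.46). CG15399 went from 158 to 19.6 and 399 (at least 19.7-fold, fitted -3.54). The nuclear envelope gene spag4 went from 29.4 to 5.07 and 76.6 (at least 3.75-fold, fitted -2.14), with a fall against control of at least 1.3-fold only. CG6675 went from 114 to 7.87 and 245 (at least 12.1-fold, fitted -3.45). The gene neo went from 121 to 6.53 and 285 (at least 14.0-fold, fitted -3.74). A probe set with no gene symbol listed went from 134 to 42.3 and 334 (difference -2.58). CG12983 rose from 313 to 708 in arrays labelled comr and fell to 133 in can (difference 2.28). The folate enzyme gene Nmdmc rose from 47.1 to 121 and fell to 13.2 (at least 5.97-fold, fitted 2.23). None of the 8 was called in opposite directions with ribosomal protein centring, 1 with array median centring, 3 with spiked-control centring and 4 with quantile normalisation, so these opposite calls depend on the scaling. Counting other probe sets too, these scalings gave 17, 3, 8 and 5 opposite calls. Ribosomal protein centring moved all changes by -1.10 in arrays labelled comr and -1.32 in can. The rises among the 8 were 1.01 to 1.27, so none could stay called. Differences between the mutants moved by 0.22 only.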

How the results depend on the processing

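Alternatives centred on spiked controls and those leaving out the array with most accessory gland signal per group were chosen after seeing the data. The correlation of changes stayed above 0 in every setting, and the cause was not tested where a value moved, except that a looser or stricter fold or filter changes counts by its construction. Counts are given as lower and higher. With an offset of 64 the counts moved to 1492 higher in arrays labelled comr, 946 higher in can, 503 and 150 between the mutants and 755 higher in both, with a correlation of changes of 0.902; with an offset of 1 to 678 higher between the mutants and a correlation of 0.860. Ribosomal protein centring gave 4138 and 431 in arrays labelled comr, 5012 and 89 in can, 781 higher between the mutants, and 3825 and 58 in both. Array median centring gave 1260 higher in can and 1069 higher in both. Spiked-control centring gave 4431 higher in arrays labelled comr, 3288 in can, 676 between the mutants and 3028 in both, and 9 lists between the mutants, in a fit where limma took each spread from the intensity trend alone, so that its calls do not weigh the spread of single probe sets. Without a minimum fold there were 2799 and 4925, 2311 and 4611, 2348 and 2437, and 2066 and 4137 in both; at 4-fold 1067 and 587, 582 and 225, 439 and 28, and 549 and 152. The correlation was 0.878 without a filter, 0.893 with 50% left out, 0.872 with quantile normalisation, 0.888 with 1 probe set per gene and 0.882 with less accessory gland signal. Lists between the mutants numbered 10 without a filter, and with an estimated correlation 0, 2 and 0 lists passed in the 3 comparisons. With each array left out the counts were 1575–1650 and 2778–2827 for arrays labelled comr, 1235–1284 and 1993–2055 for can, 995–1005 and 425–468 between the mutants, 1140–1183 and 1663–1722 in both, with correlations of 0.881–0.886 and 13–13, 12–12 and 4–6 lists. The replicate block gave 1614 and 2813, 1259 and 2024, 1002 and 438, 1162 and 1697, a correlation of 0.885 and 13, 12 and 5 lists. Where a named gene was called, or a list passed its test, in the main or the other fit, the direction turned with ribosomal protein centring alone: bw in arrays labelled comr (-1.06), and in can nht (-0.0924), Taf5 (-0.17), mip120 (-0.22), Cks85A (-0.0119), COX5B (-0.17), ND-51 (-0.20), zpg (-0.0589), aub (-0.0602), chinmo (-1.01), Gld (-1.20), Obp99b (-1.06), vkg (-0.30), comr (-0.16), can (-1.14) and the general respiratory chain list (-0.45). Not counted here are genes called in neither fit, such as comr (-0.52) and Gld (-0.73) in arrays labelled comr, and lists whose median turned while their test kept its direction, such as general proteasome subunits (-0.0848 and -0.31). Of 164 called pairs of a named gene and a comparison, 159 were called in every fit with 1 array left out, and 0 of all 189 pairs changed direction there. With the direction kept, an offset of 64 took 21 of the 189 pairs below the threshold, ribosomal protein centring 46, quantile normalisation 5, array median centring 9 and a 4-fold minimum 59. Pairs called in the main fit whose direction turned with ribosomal protein centring lost the threshold as well and are not in the 46. Settings that alter only p values or thresholds gave no other value for the correlation, and list counts had none without a minimum fold, at 4-fold or with 1 probe set per gene. The 50% filter left 167 pairs and 69 list results with a value. Signal over background limits the rest: dim groups at or under 20.3 give lower bounds of a fold, and the dimmest 30% of probe sets were not tested.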

Other observations

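The lists on TFIIH, glycolysis and mitochondrial import and the comparison of chromosomes were all chosen after the data had been seen. Their p values come from the data that led to the choice, so they describe these patterns and do not test them. The lists fixed beforehand were adjusted without these later lists, so the adjusted p values of the later lists cannot be set beside theirs. Subunits of TFIIH, the factor of transcription initiation and DNA repair, rose in both mutants in every scaling by their median: 7 of 9 were called higher in arrays labelled comr (camera adjusted p = 0.00214, adjusted p = 0.0387 with an estimated correlation) and 6 of 9 in can (adjusted p = 0.00286, adjusted p = 0.0351 with an estimated correlation). Mat1 was 97.7 ± 15.9 in control, 984 ± 66.9 in arrays labelled comr and 859.7 ± 71.6 in can, Xpd 16.5 ± 2.14, 263 ± 9.91 and 298 ± 43.5, and hay 17.8 ± 6.07, 345 ± 14.8 and 118 ± 3.41.

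Testis paralogs of glycolysis and most of those of mitochondrial import fell. All 6 tested testis glycolytic paralogs fell in both mutants (camera adjusted p = 1.09e-05, adjusted p = 0.0424 with an estimated correlation in arrays labelled comr; 7.14e-06, and adjusted p = 0.0351 with an estimated correlation in can), the hexokinase Hex-t2 from 1877 ± 99.0 to 7.07 ± 4.37 and 221 ± 14.2. General glycolytic enzymes went both ways, 3 down and 3 up of 8 in arrays labelled comr (camera adjusted p = 0.748) and 2 down and 3 up in can (camera adjusted p = 0.452), with medians that turned below 0 with ribosomal protein centring in both and with array median centring in can. Ald1 was 1196 ± 63.6, 259.7 ± 30.1 and 453 ± 50, and Gapdh1 182 ± 10.1, 610 ± 49.8 and 575 ± 6.03. Testis paralogs of the mitochondrial import machinery fell for 7 of 8 in arrays labelled comr (camera adjusted p = 1.09e-05, adjusted p = 0.0387 with an estimated correlation) and 6 of 8 in can (1.20e-04, and adjusted p = 0.0351 with an estimated correlation), with tomboy20 at 1515 ± 127, 2.20 ± 1.51 and 324 ± 13.1. The general import genes had 1 fall of 6 in arrays labelled comr, Tim13 (camera adjusted p = 0.176), and in can a fall of Tim13 and a rise of Tom40 (camera adjusted p = 0.215), with medians above 0 with spiked-control centring in both. Between the mutants, arrays labelled comr were lower for 5 of 6 testis glycolytic paralogs (camera adjusted p = 0.00104, adjusted p = 0.159 with an estimated correlation) and 6 of 8 testis import paralogs (5.74e-05, adjusted p = 0.0630 with an estimated correlation), and higher for 1 of 9 TFIIH subunits, hay (camera adjusted p = 0.277). Camera adjusted p was 0.678 for general glycolytic genes with 0 called, and 0.277 for general import genes, with Tim13 lower.

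Fewer X-linked than autosomal genes fell, with autosomal standing for arms 2L, 2R, 3L and 3R, without chromosome 4. In arrays labelled comr 14.0% of 1379 X-linked genes were lower against 18.4% of 6790 autosomal genes (two-sided Fisher's exact p = 6.56e-05), and in can 8.48% against 14.9% (Fisher's exact p = 3.71e-11). Rises were 25.2% against 31.1% in arrays labelled comr (Fisher's exact p = 1.18e-05) and 21.4% against 21.5% in can (Fisher's exact p = 0.971). With ribosomal protein centring the falls were 41.7% against 41.8% and 47.7% against 51.0%, and with spiked-control centring rises in can were 34.8% against 34.2%. On chromosome 4, 1 of 35 genes was lower in arrays labelled comr and 0 in can. Genes are not independent replicates, and 4 such tests were made.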
